A study of Rattus norvegicus with 16 samples.

How the data were processed

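Total RNA from rat brain was hybridised to 16 single-channel (Cy3) Agilent arrays, 1 per sample: 5 normal controls, 5 rats with middle cerebral artery occlusion (MCAo) and saline, and 6 rats with MCAo and an intravenous infusion of human umbilical mesenchymal stem cells (hUMSC). The labels give an age of 8 weeks, an infusion of 1000000 cells and sampling 72 hours after occlusion. They do not give the hemisphere or region, the time of infusion or the sex. The labels' RNA protocol names a blood RNA kit with globin reduction although the tissue is given as brain. Over the 16 arrays, the mean log2 level of general neuronal genes, scaled as described below, was 1.81 to 2.73. Neutrophil genes lay at -6.15 to -2.85, T and NK cell genes at -5.72 to -4.06 and red blood cell genes at -1.12 to 1.98. These levels argue against blood as the tissue. Which kit was used could not be settled from the files.

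The scanner files hold, per the file headers, the processed signal as an intensity: background-subtracted and detrended within each array by Agilent Feature Extraction 11.0.1.1, with no scaling between arrays. The submitters' notes write the version as 100.0.1.1. The median spot signal and the median local background are also intensities per the file headers, and the spot marks (well above background, outlier, saturated) are flags per the file headers. The deposited value table is an intensity too. It was checked against the scanner files and equals the mean of the processed signal over all spots of a probe, neither scaled nor centred, with array medians of 207 to 277. Each array has 62976 spots, of which 58717 are not controls and belong to 30367 probes. The share of probes well above background was 72.3% to 77.6%. No probe was saturated on any array. The number of arrays limits the precision.

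Spots marked as outliers were dropped, the log2 processed signals of the remaining spots were averaged per probe, and the array's 75th percentile was subtracted. Probes with no usable spot on some array were left out, 9 in number. Probe accessions were matched to gene symbols without their version: 18355 probes matched 15443 symbols and 12012 had no match, and 94% of the curated mRNA accessions had a symbol. The array annotation names an older build of the rat genome, and genome positions were not used here. A probe was tested if it was well above background on at least 5 arrays, and a gene with several such probes was represented by the one with the highest mean. This left 20471 features, called genes below, of which 12610 have a symbol.

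The 3 comparisons (saline minus control, hUMSC minus saline, hUMSC minus control) came from a single limma model with a mean per group over all 16 arrays, which leaves 13 residual degrees of freedom. Tests were two-sided moderated tests in limma 3.58.1 (R 4.3.3, with data.table version 1.17.8), adjusted by Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. Errors of fold changes are standard errors (SE) of that model. Counts with a change of at least 2-fold are given beside the full counts. For a gene that was not well above background on any array of a group, the fold is a lower bound against the lowest signal well above background. For 30 gene lists with at least 5 measured members, camera in limma tested whether a list moved against the other genes, with a preset correlation between members of 0.01, adjusted over the lists of a comparison. The same test was run with the correlation estimated from the arrays. The rotation test fry was run as an alternative: its p tests whether a list's genes move on balance one way, and it does not compare them with other genes. Of the genes listed, 6 of 15 in leukocyte adhesion also stand in another list, as do 1 or 2 in each of 6 other lists, and none in the remaining lists. The lists hold markers of the cell types that brain tissue and blood contain, and the tissue itself expresses most of their genes at some level.

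The occlusion score of an array is the mean, over genes that changed at least 2-fold between all 11 occluded arrays and the controls, of the change from the control mean in the direction of that change. It is scaled so that the controls average 0 and the occluded arrays 1. The scores of hUMSC and saline arrays were compared by a two-sided exact permutation test over the 462 assignments of the 11 arrays. The score's genes were chosen on both occluded groups together, so the choice favours neither.

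Genes named in the text followed a rule: per comparison and direction the 6 largest changes among called genes whose groups did not overlap and whose probe was well above background on every array of the higher group, up to 3 called members per list, and a few genes given in every comparison whatever their values (Gfap, Il1b, Tnf, Ccl2, Cd68, Hmox1, Hspb1, Bdnf, Vegfa, Mmp9). Il6 was not well above background on enough arrays, and no probe was matched to Rbfox3. The groups, tests, lists, alternatives and this rule were fixed before the data were examined. The arrays lie on 2 slides: slide 1 holds 3 controls, 3 saline and 2 hUMSC arrays, and slide 2 holds 2 controls, 2 saline and 4 hUMSC arrays.

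Alternatives were normexp background correction with an offset of 50, quantile normalisation, median scaling, the deposited values, no filter on dim probes, a filter on all 16 arrays, the mean of a gene's probes, only the arrays of the groups compared, slide as a block, each slide alone, a trended robust variance, array weights, replicate numbers as a block, and leaving out each array in turn. Added after values were seen were fits without saline replicates 1 and 5 together or without other pairs of saline arrays, the occlusion score as a covariate, and the gene lists, the score and the named genes within each slide. Normexp used the median spot signal because the files hold no mean signal. The analysis was tested on simulated data with 200 changed genes per comparison: a log2 change of 1 was recovered in 79% (saline against control), 88% (hUMSC against saline) and 86% (hUMSC against control) of them. Simulated genes were independent, with a gene's spread equal in all groups. The real arrays had correlated genes and unequal spreads, so these shares need not hold for them.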

Results

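Gene expression was measured in rat brain tissue 72 hours after middle cerebral artery occlusion (MCAo), a model of ischaemic stroke in which a main artery of a hemisphere is blocked. The 16 arrays comprised 5 normal controls, 5 occluded rats given saline and 6 occluded rats given human umbilical mesenchymal stem cells intravenously (hUMSC). Between 72.3% and 77.6% of the probes on an array were well above background. The correlation between arrays of a group, across genes, was 0.992 to 0.996 in controls, 0.978 to 0.993 in saline and 0.980 to 0.993 in hUMSC. Genes are not independent replicates, so these values describe the arrays only. The median standard deviation (SD) of a gene within a group was 0.109 in controls (n = 5), 0.209 in saline (n = 5) and 0.191 in hUMSC (n = 6), on the log2 scale. The first principal component held 64.9% of the variance and placed all 5 controls at one end and hUMSC replicates 5 and 6 at the other. Saline replicates 1 and 5 lay between the controls and the remaining occluded arrays. The list p-values with the preset correlation compare genes with other genes as nearly independent units, so they mostly leave out the spread between animals. For proliferation the correlation estimated from the arrays was 0.90. The p-values of single genes and of the exact permutation tests measure the spread between these samples. In the limma model that spread is pooled over all 16 arrays. For hUMSC against saline the SE and p-values of that model therefore also rest on the controls, whose spread was smaller.

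Saline against normal control asks what differed from intact brain 72 hours after occlusion. The labels name no sham-operated group, so effects of surgery and of the saline cannot be told apart from those of occlusion. Genes of phagocytes, dividing cells and reactive astrocytes rose, and genes of striatal neurons and of neuronal activity fell, as lists with the preset correlation and not with an estimated one (adjusted p = 0.226 to 0.230). Gpnmb, a glycoprotein of phagocytes loaded with debris, rose by 5.15 ± 0.50 (log2 change ± SE; adjusted p = 7.58e-05), and Spp1 (osteopontin) rose by 5.10 ± 0.49. The chemokine Ccl2, which recruits monocytes, rose by 5.64 ± 0.70, and Gfap, the intermediate filament of reactive astrocytes, rose by 1.92 ± 0.30. Adora2a, the adenosine receptor of striatal projection neurons, fell by 1.37 ± 0.21, and Arc, an activity-regulated synaptic gene, fell by 2.05 ± 0.44. Each of these 6 genes lay outside the range of all 5 controls in all 5 saline arrays, which the naming rule required of Ccl2 and Arc.

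Of 20471 genes, 2924 were higher and 2657 lower in saline than in control, with 913 higher and 47 lower by at least 2-fold. The 2-fold counts were 503 and 24 with normexp background correction and 1373 and 231 without saline replicates 1 and 5, and 82, 29 and 100 genes were lower by 2-fold without saline replicates 1, 4 and 5 in turn. With median scaling and array weights 72 and 121 genes were lower by 2-fold, and within slide 2 the counts were 0 and 1. The split between directions depended on the scaling: 52.4% of the called genes were higher, against 32.7% (2377 higher, 4888 lower) with median scaling. The largest rises among the genes eligible to be named were of Serpina3n (7.13 ± 1.31), a protease inhibitor of reactive astrocytes, Mmp12, a macrophage elastase that was at least 25.7-fold higher, Ccl2, Fabp4 (5.60 ± 0.76), a fatty acid carrier, Cd8a, a T cell co-receptor that was at least 33.9-fold higher, and Fcnb (5.40 ± 0.49), a ficolin of myeloid cells. Mmp12 and Cd8a were not well above background on any control array, and Serpina3n and Fabp4 were on 1 of 5. With normexp background correction, whose offset of 50 shrinks changes of dim probes, the log2 changes were 5.07 for Serpina3n, 2.48 for Mmp12, 2.79 for Fabp4, 2.65 for Cd8a, 3.60 for Fcnb and -0.62 for Hal, all past the test. The largest falls were of Hal (histidine ammonia-lyase), at least 4.80-fold lower, Egr2 (-2.16 ± 0.45), Cort (cortistatin, -2.09 ± 0.54), Arc, Egr4 (-1.97 ± 0.50) and Nr4a1 (-1.81 ± 0.33).

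Markers of phagocytic macrophages rose (median log2 change 1.99): 20 of 25 measured members rose and 5 did not pass the test, or 21 adjusted over the list alone. Cd68, a lysosomal protein of macrophages, rose by 3.54 ± 0.44. Of the 22 lists called in this comparison with the preset correlation, none was called with an estimated correlation. For phagocytic macrophages the adjusted p was 7.82e-17, with adjusted p = 0.226 with an estimated correlation. Proliferation genes rose with a median of 2.39, in 25 of 26 members over all genes and 26 adjusted over the list alone. Ccna2, a cyclin of S phase, rose by 3.59 ± 0.40, Cdk1, the kinase of mitotic entry, by 3.47 ± 0.45, and Aurkb by 2.22 ± 0.38 (1.15 with normexp). The adjusted p of proliferation was 4.76e-20, and the adjusted p = 0.226 with an estimated correlation. In reactive astrocytes 18 of 22 members rose, or 20 adjusted over the list alone, with a median of 1.53, or 1.33 with unmeasured controls at their bound. As a list it had an adjusted p of 2.29e-11, and adjusted p = 0.226 with an estimated correlation. Vim, an intermediate filament, rose by 2.59 ± 0.41 and Hspb1, a small heat shock protein, by 3.06 ± 0.65. Homeostatic microglia rose in 8 of 12 members by both counts (8 adjusted over the list alone), with a median of 0.54 and Csf1r at 1.21 ± 0.18. This gave an adjusted p of 8.27e-06, and adjusted p = 0.226 with an estimated correlation.

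The mean level of phagocyte genes was 0.15 in saline replicate 1 and -0.61 in saline replicate 5, against 1.32 to 1.52 in the other saline arrays and -1.66 to -1.41 in controls. For proliferation the means were -1.91 and -2.48 in these arrays, against -0.67 to -0.51 in the other saline arrays and -3.51 to -3.36 in controls. For striatal projection neurons they were 0.01 and 0.17, against -0.74 to -0.43 in the other saline arrays and 0.54 to 0.69 in controls.

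Inflammatory and matrix genes rose. Cytokines and chemokines rose in 18 of 27 members, the same number adjusted over the list alone, with a median of 1.37, or 1.20 with unmeasured controls at their bound. Il1b rose by 2.05 ± 0.36 (0.999 with normexp) and Tnf by 0.90 ± 0.20, both early inflammatory cytokines, and the neutrophil chemokine Cxcl1 was at least 7.04-fold higher (log2 change 1.25 with normexp). Its members together had an adjusted p of 7.90e-09, and adjusted p = 0.226 with an estimated correlation. Complement rose in 15 of 19 members, or 18 adjusted over the list alone, with a median of 1.33, and its receptors C5ar1 and C3ar1 rose by 3.04 ± 0.46 and 2.28 ± 0.35 (2.01 and 1.27 with normexp). The list had an adjusted p of 4.87e-11, and adjusted p = 0.226 with an estimated correlation. Antigen presentation rose in 15 of 19, or 17 adjusted over the list alone, with a median of 1.09. Its class II gene RT1-Da rose by 2.10 ± 0.36 and the immunoproteasome gene Psmb8 by 1.91 ± 0.29, with an adjusted p of 2.54e-10 and an adjusted p = 0.226 with an estimated correlation. Leukocyte adhesion rose in 9 of 12 by both counts (9 adjusted over the list alone), with a median of 1.23 and Glycam1, a selectin ligand, at 2.61 ± 0.51. As a list it had an adjusted p of 9.66e-07, and adjusted p = 0.226 with an estimated correlation.

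The extracellular matrix and its proteases rose in 20 of 27 members, or 22 higher and 1 lower adjusted over the list alone, with a median of 1.04. Timp1, an inhibitor of metalloproteinases, rose by 3.34 ± 0.58 and Mmp9, a gelatinase, by 1.40 ± 0.32. This gave an adjusted p of 5.69e-11, and adjusted p = 0.230 with an estimated correlation. The interferon response rose in 12 of 24, or 15 adjusted over the list alone, with a median of 0.76 and Gbp2 at 1.53 ± 0.28. Its members together had an adjusted p of 4.50e-07, and adjusted p = 0.230 with an estimated correlation. In apoptosis and p53, 13 of 26 rose and 1 fell, or 15 and 1 adjusted over the list alone, with a median of 0.39. The kinase of necroptosis Ripk3 rose by 2.89 ± 0.34, with an adjusted p for the list of 3.20e-05 and an adjusted p = 0.226 with an estimated correlation. In heat shock, metallothionein and stress response, 9 of 20 rose and 1 fell, or 9 and 2 adjusted over the list alone, with a median of 0.30. Hmox1, haem oxygenase, rose by 2.47 ± 0.52 and the stress transcription factor Atf3 by 2.42 ± 0.42. The list had an adjusted p of 0.0117, and adjusted p = 0.230 with an estimated correlation.

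Neutrophil markers rose with a median of 1.46: 5 of 9 rose and 1 fell, or 7 and 1 adjusted over the list alone, and Trem1 was at least 6.56-fold higher (log2 change 1.41 with normexp). As a list it had an adjusted p of 0.000842, and adjusted p = 0.226 with an estimated correlation. S100a8 and S100a9, calcium-binding proteins of neutrophils, had changes of 1.52 ± 0.59 (adjusted p = 0.0684) and 1.46 ± 0.62 (adjusted p = 0.0912). T and NK cells rose as a list with a median of 0.22, although 3 of 16 members rose and 1 fell by both counts (3 and 1 adjusted over the list alone). The other 12 did not pass. The list's mean of 0.59 included Cd8a at 5.59 (2.65 with normexp), which was not well above background on any control array. A rise across the T and NK cell genes is therefore not shown. The list had an adjusted p of 0.0427, and adjusted p = 0.421 with an estimated correlation. The call of T and NK cells was lost with fry (adjusted p = 0.0507), with quantile normalisation and within slide 1. Not past the test were B cells (median 0.26, adjusted p = 0.305), red blood cells (0.03, 0.665; the labels state that globin transcripts were depleted), resting astrocytes (-0.22, 0.428), oligodendrocyte precursors (-0.05, 0.818), endothelium and tight junctions (0.18, 0.217), pericytes and smooth muscle (0.04, 0.818), choroid plexus and ependyma (-0.18, 0.902), and growth, neurotrophic and angiogenic factors (0.03, 0.646). For oligodendrocyte precursors the median was negative, and the mean (0.03) and the test were positive. Within the growth factor list Igf1 rose by 1.85 ± 0.34, and Bdnf, a neurotrophin, and Vegfa, the main angiogenic factor, fell by 1.19 ± 0.31 and 0.87 ± 0.19. The other probes of Vegfa had smaller changes, of -0.76, -0.51 and -0.48.

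Neuronal lists fell. Striatal projection neurons fell in 13 of 16 members, or 14 adjusted over the list alone, with a median of -0.94; Rgs9, a striatal regulator of G protein signalling, fell by 1.35 ± 0.23 and Pde10a, a striatal phosphodiesterase, by 1.14 ± 0.22. Its members together had an adjusted p of 1.78e-08, and adjusted p = 0.226 with an estimated correlation. Immediate early genes, which are induced by neuronal firing, fell in 13 of 20 members and rose in 2 by both counts (13 and 2 adjusted over the list alone), with a median of -0.69. Fosl1 was a riser, at 2.60 ± 0.49 (1.44 with normexp). The list had an adjusted p of 0.000602, and adjusted p = 0.230 with an estimated correlation. Glutamatergic neurons and receptors fell in 13 of 21, or 18 adjusted over the list alone, with a median of -0.49; Camk2b, a kinase of excitatory synapses, fell by 0.73 ± 0.16 and Nrgn (neurogranin) by 0.74 ± 0.18. As a list it had an adjusted p of 2.50e-06, and adjusted p = 0.293 with an estimated correlation. GABAergic interneurons and receptors fell in 9 of 21, or 11 adjusted over the list alone, with a median of -0.29, an adjusted p of 0.000770 and an adjusted p = 0.365 with an estimated correlation. General neuronal genes fell in 7 of 16, or 8 adjusted over the list alone, with a median of -0.29 and the synaptic vesicle gene Syn1 at -0.59 ± 0.14. This gave an adjusted p of 0.000602, and adjusted p = 0.365 with an estimated correlation.

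Potassium and sodium channels fell in 13 of 24, or 16 adjusted over the list alone, with a median of -0.42 and the channel subunit Scn4b at -0.94 ± 0.18. Its members together had an adjusted p of 1.87e-06, and adjusted p = 0.317 with an estimated correlation. Mature oligodendrocytes fell in 9 of 17 and rose in 1, or 11 and 1 adjusted over the list alone, with a median of -0.37. The myelin genes Opalin and Cnp fell by 0.94 ± 0.12 and 0.61 ± 0.14, with an adjusted p for the list of 0.000602 and an adjusted p = 0.241 with an estimated correlation. Cholesterol synthesis fell in 13 of 20, or 17 adjusted over the list alone, with a median of -0.38. The list had an adjusted p of 5.71e-06, and adjusted p = 0.230 with an estimated correlation.

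With slide as a block 3432 genes were higher and 3209 lower. Within slide 1 there were 2079 and 973, and within slide 2 (2 arrays against 2) limma called 0 and 1, with 2455 genes at an unadjusted p under 0.05. Without saline replicates 1 and 5, a choice made after their levels were seen, 4049 genes were higher and 4992 lower. The number of lower genes was 1676, 1700, 1543, 1767 and 1711 without control replicates 1 to 5 in turn, 1154, 1259 and 1283 without saline replicates 2, 3 and 4, and 3990 without saline replicate 5.

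**Figure D1:**
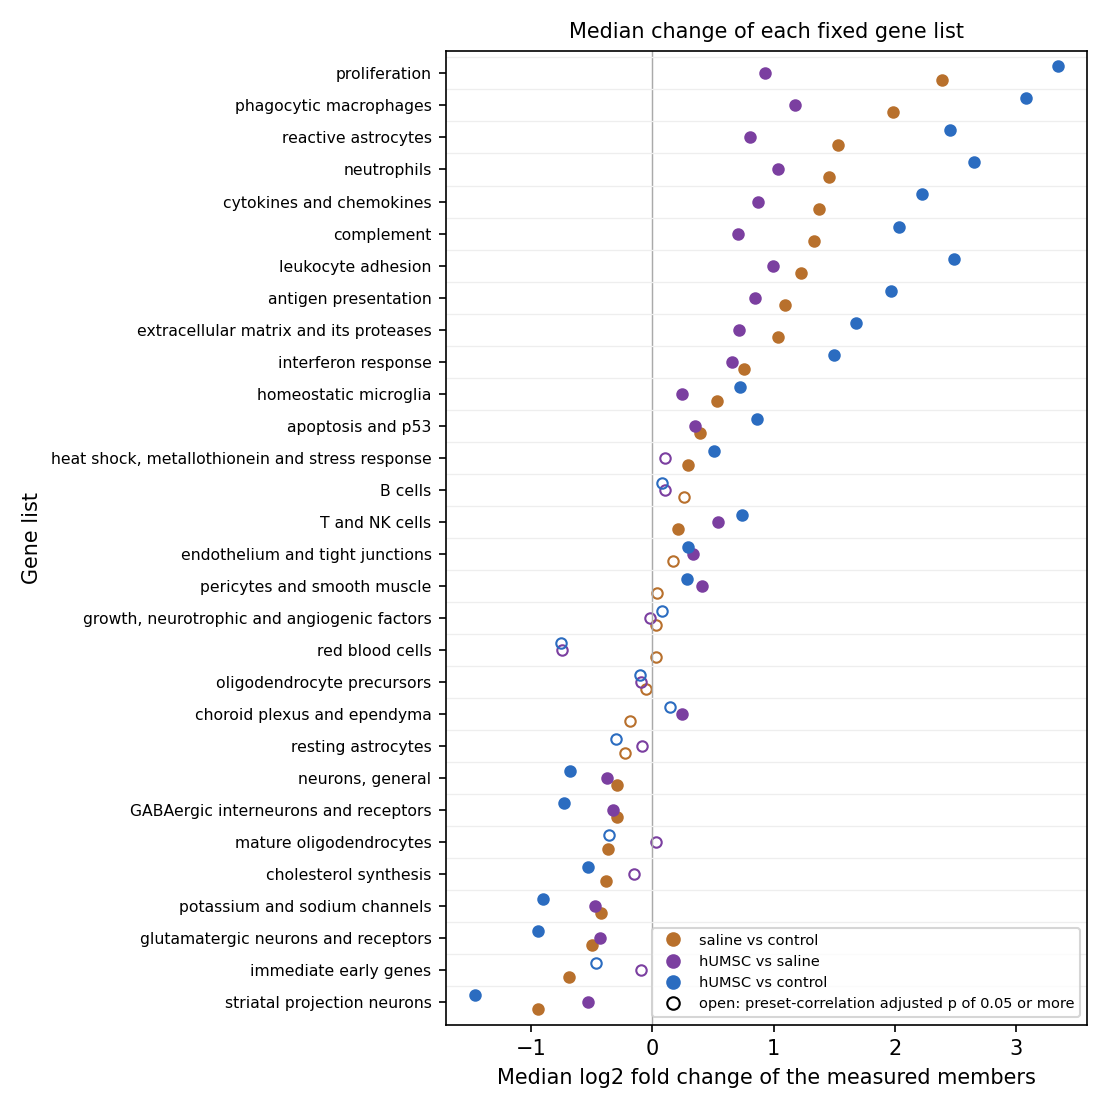
Median log2 fold change of the measured members of each of the 30 gene lists (horizontal axis), in the 3 comparisons (colours); open circles have an adjusted p of 0.05 or more with the preset correlation. In hUMSC against control the median was 3.35 for proliferation and -1.46 for striatal projection neurons.

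The hUMSC group against normal control asks what distinguished occluded, cell-treated brain from intact brain. Genes of phagocytes, dividing cells and reactive astrocytes rose and genes of neurons fell, as lists with the preset correlation and not with an estimated one. Serpina3n rose by 8.23 ± 1.26 (adjusted p = 7.98e-05), Ccl2 by 7.72 ± 0.67 (adjusted p = 2.43e-06) and the monocyte chemokine Ccl7 by 7.19 ± 0.69 (adjusted p = 3.54e-06). Mmp12 was at least 47.0-fold higher, and Gfap rose by 2.94 ± 0.29. Cort fell by 3.24 ± 0.52, Egr4 by 2.80 ± 0.48, Hal by 2.52 ± 0.37, Arc and Egr2 both by 2.48 ± 0.43, and C14h1orf146 by 2.30 ± 0.30. Each of these lay outside the range of all 5 controls in all 6 hUMSC arrays. The naming rule required this of the largest rises and falls, so it is no separate support for them. Serpina3n and Ccl7 were well above background on 1 of 5 control arrays, Mmp12 on none, and Hal on 1 of 6 hUMSC arrays. With normexp the log2 changes were 5.99 for Serpina3n, 4.50 for Ccl7, 3.03 for Mmp12, -0.69 for Hal and -1.10 for C14h1orf146, all past the test.

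In this comparison 5057 genes were higher and 7643 lower, with 1727 and 491 by at least 2-fold. With normexp 238 were lower by 2-fold, and within slides 1 and 2 the number was 1181 and 285. The median change of all genes was -0.13, and -0.17 with median scaling, so small falls are to be read against that shift. Within slide 1, 4758 were higher and 6124 lower; within slide 2, 3030 and 3154; with slide as a block, 5342 and 8365.

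All members of 3 rising lists passed: phagocytic macrophages (25, median 3.08, adjusted p = 2.74e-15), proliferation (26, median 3.35, adjusted p = 1.41e-16) and reactive astrocytes (22, median 2.45, or 2.17 at the bound, adjusted p = 9.18e-12). Antigen presentation rose in all 19 (median 1.97, or 1.86 at the bound, adjusted p = 9.18e-12). Complement rose in 18 of 19 (2.04, adjusted p = 1.02e-10), the matrix list in 26 of 27 (1.68, adjusted p = 3.12e-12), leukocyte adhesion in 11 of 12 (2.49, adjusted p = 5.65e-08) and homeostatic microglia in 8 of 12 (0.72, adjusted p = 0.000178). Cytokines and chemokines rose in 22 of 27 and fell in 2 (2.23, adjusted p = 1.30e-09), the interferon response rose in 21 of 24 and fell in 1 (adjusted p = 4.06e-09), and apoptosis and p53 rose in 18 of 26 and fell in 3 (0.86, adjusted p = 1.46e-05). Neutrophils rose in 7 of 9 (2.65, adjusted p = 0.000331) and T and NK cells in 10 of 16 (0.74, adjusted p = 0.000223). With an estimated correlation each of these 13 lists had an adjusted p = 0.211. The counts adjusted over the list alone were the same for these 13 lists. Spp1 rose by 6.01 ± 0.47, Timp1 by 4.58 ± 0.56, Il1b by 3.75 ± 0.34 (2.11 with normexp) and Ccna2 by 4.73 ± 0.39.

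Vascular and stress lists rose as well. Endothelium and tight junctions rose in 9 of 17 (median 0.30, adjusted p = 0.00101, and adjusted p = 0.225 with an estimated correlation), with Tie1, an endothelial receptor kinase, at 1.26 ± 0.20. Pericytes and smooth muscle rose in 6 of 14 and fell in 1 (0.29, adjusted p = 0.0255, and adjusted p = 0.336 with an estimated correlation), with Tagln, an actin-binding protein of smooth muscle, at 2.81 ± 0.30. Heat shock, metallothionein and stress response rose in 10 of 20 and fell in 6 (0.51, adjusted p = 0.0206, and adjusted p = 0.265 with an estimated correlation), with Hspb1 at 4.30 ± 0.62. The counts adjusted over the list alone were the same for these 3 lists.

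All members fell in general neuronal genes (16, median -0.68, adjusted p = 1.89e-05), glutamatergic neurons and receptors (21, -0.94, adjusted p = 1.60e-06) and potassium and sodium channels (24, -0.90, adjusted p = 1.30e-07). With an estimated correlation each had an adjusted p = 0.266. Striatal projection neurons fell in all 16 (-1.46, adjusted p = 6.57e-07, and adjusted p = 0.218 with an estimated correlation), and GABAergic interneurons and receptors in 19 of 21, or 20 adjusted over the list alone (-0.73, adjusted p = 4.14e-05, and adjusted p = 0.272 with an estimated correlation). Cholesterol synthesis fell in 17 of 20 and rose in 1 (-0.53, adjusted p = 0.000202, and adjusted p = 0.285 with an estimated correlation). For the other 5 of these 6 lists the counts adjusted over the list alone were the same. Among genes given in every comparison, Cd68 rose by 4.87 ± 0.42, Hmox1 by 3.71 ± 0.49, Mmp9 by 2.41 ± 0.30 and Tnf by 1.74 ± 0.19, and Vegfa fell by 1.18 ± 0.18. Adora2a fell by 1.96 ± 0.20, Camk2b by 1.42 ± 0.15 and Bdnf by 1.65 ± 0.29.

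Not past the test were B cells (median 0.08, adjusted p = 0.385), red blood cells (-0.75, 0.611), resting astrocytes (-0.30, 0.379), mature oligodendrocytes (-0.36, 0.0755), oligodendrocyte precursors (-0.10, 0.993), choroid plexus and ependyma (0.15, 0.0902), growth, neurotrophic and angiogenic factors (0.08, 0.379) and immediate early genes (-0.46, 0.191). Of the immediate early genes 11 of 20 fell and 3 rose, Fosl1 by 4.08 ± 0.47 (2.49 with normexp). Of the resting astrocyte genes 8 of 15 fell and 4 rose, and Kcnj10, the inward rectifier channel of astrocytes, fell by 0.70 ± 0.13 (0.25 with normexp).

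The changes of the 2 occluded groups against the controls correlated across genes at r = 0.941. Both comparisons used the same controls, and with the controls split between the comparisons r was 0.876. Simulations with unchanged groups gave 0.517, with a gene's spread set equal in all groups. The real controls varied less (median SD 0.109 against 0.209 and 0.191), so 0.517 is not the value these controls alone would give. Of the genes higher in saline, 2830 were also higher in hUMSC, and of the genes lower in saline, 2530 were also lower. Independent lists would share 722 and 992, but the shared controls raise such an overlap and the amount was not simulated. Kcnj8, a potassium channel subunit of pericytes, was the 1 gene called in opposite directions, at -0.48 ± 0.15 in saline and 0.57 ± 0.14 in hUMSC. Its fall in saline had an adjusted p of 0.0254, which became 0.0592 without control replicate 3 and 0.0670 without saline replicate 3. Of the genes called in saline, 89.4% had a larger change in hUMSC.

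**Figure D2:**
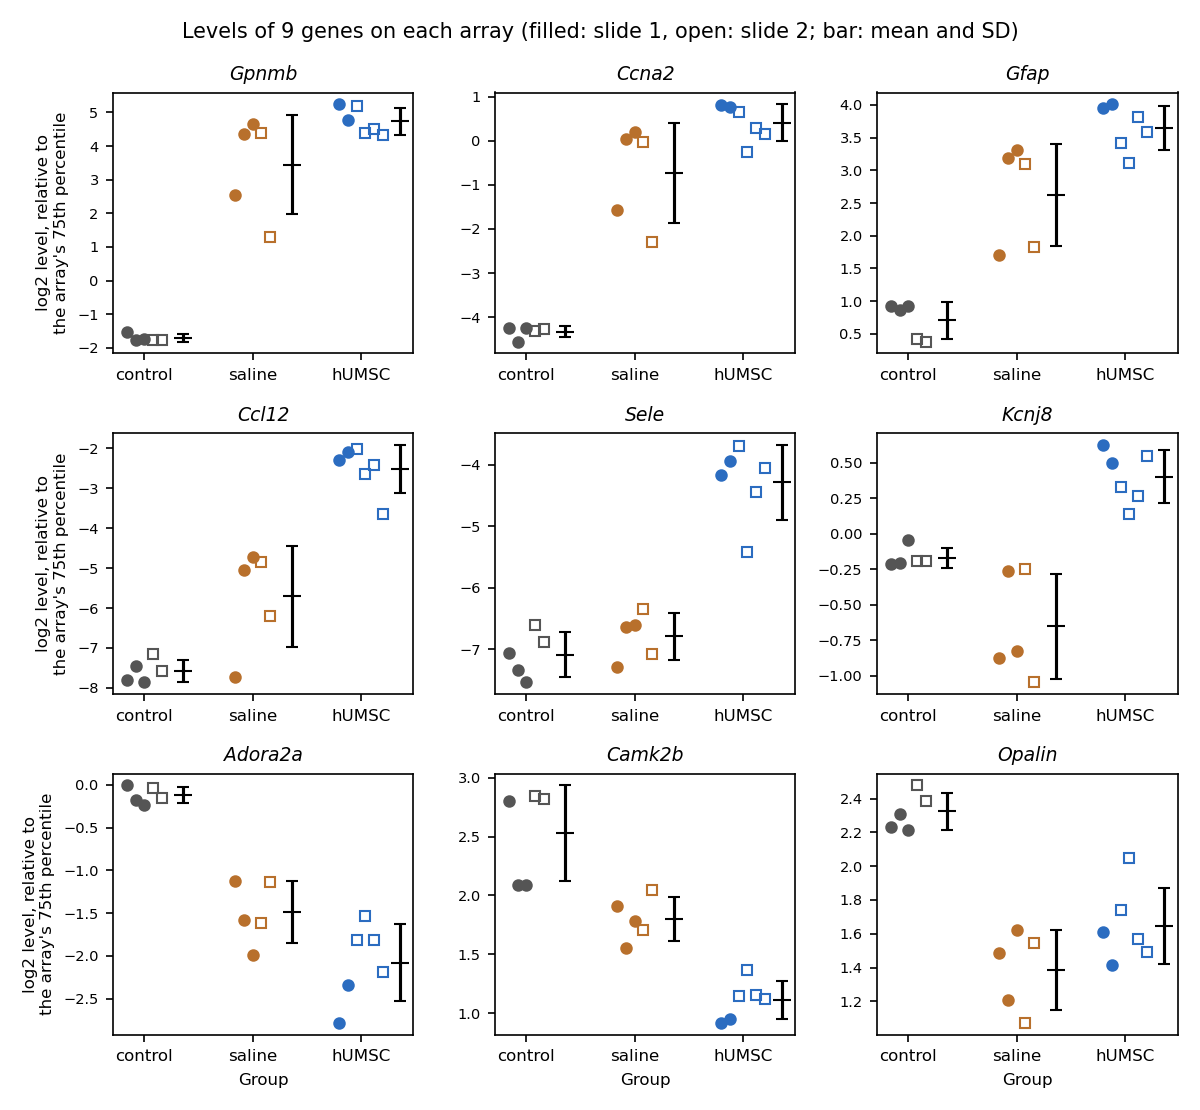
Log2 level of 9 genes on each array relative to its 75th percentile (vertical axis) in the 5 control, 5 saline and 6 hUMSC arrays; filled points are slide 1, open points slide 2, and bars show the mean and SD of a group. Gpnmb was at 2.54 and 1.30 in saline replicates 1 and 5 and at 4.36 to 4.66 in the other saline arrays.

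The hUMSC group against saline asks what the infused cells changed after occlusion. Inflammatory genes were higher in hUMSC and neuronal genes lower, as lists with the preset correlation. None of the 21 lists was called with an estimated correlation, and without saline replicates 1 and 5, which stood nearest to the controls, 23 of 2624 genes were called. Ccl12, a monocyte chemokine, was higher by 3.19 ± 0.46 (adjusted p = 0.00378), and Sele, the selectin of activated endothelium, by 2.51 ± 0.27 (adjusted p = 0.00105). Kcnj8 was higher by 1.06 ± 0.14 (adjusted p = 0.00293). Ppp2r2c, a regulatory subunit of protein phosphatase 2A, fell by 0.91 ± 0.09 (adjusted p = 0.000830), and Htr2a, a serotonin receptor, fell by 0.97 ± 0.18 (adjusted p = 0.0127). All of these 5 genes separated the 6 hUMSC arrays from the 5 controls. That is a comparison with intact brain and does not bear on the difference from saline. The SE and adjusted p of hUMSC against saline rest partly on the smaller spread of the controls. Fitted on the 11 occluded arrays alone, 41 genes were called.

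In total 994 genes were higher and 1630 lower, with 207 higher and 26 lower by at least 2-fold. Of the called genes 37.9% were higher, against 50.8% (1193 higher, 1157 lower) with median scaling. Of the genes higher in hUMSC, 590 had also risen from control to saline, 21 had fallen and 383 had not passed that test. Of those lower, 284 had also fallen, 31 had risen and 1315 had not passed. The other large rises were of Reg3b (2.27 ± 0.50), Clec4a2 (2.06 ± 0.50), Mnda (2.04 ± 0.44) and Slfn4 (1.86 ± 0.40), and the other large falls of Xkr6 (-1.05 ± 0.14), Cym (-1.03 ± 0.21), Cimip4 (-0.90 ± 0.25) and Ptprn2 (-0.85 ± 0.20). Sele was well above background on 1 of 5 saline arrays. With normexp the change of Sele was 0.86, of Ccl12 1.80, of Kcnj10 -0.27, of Reg3b 1.22, of Clec4a2 1.34 and of Cimip4 -0.42, which lost its call. The other probe of Ptprn2 had a change of -0.29 (unadjusted p = 0.119).

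These counts rested on a few arrays. Without saline replicates 1 and 5, the arrays nearest to the controls, 5 genes were higher and 18 lower, and fitted on the 11 occluded arrays alone there were 8 and 33. Without saline replicate 1 there were 26 and 157, without saline replicate 5, 61 and 312, without hUMSC replicate 5, 106 and 480, without hUMSC replicate 6, 148 and 553, and without hUMSC replicate 7, 176 and 579. Leaving out saline replicate 2 gave 1772 and 2488 instead, and leaving out saline replicates 3 or 4 or hUMSC replicate 8 gave 1796, 1712 and 1714 genes higher. With 1 array left out the 2-fold counts ran from 9 to 466 higher (without saline replicates 1 and 2) and from 5 to 54 lower (without saline replicates 1 and 3). They were 3 and 0 without saline replicates 1 and 5 together, 7 and 2 on the 11 occluded arrays, 7 and 4 with array weights, 125 and 8 with normexp, and 109 and 128 within slide 1, and both were over 2 times as large with slide as a block. With slide as a block 2667 were higher and 3723 lower; within slide 1 there were 327 and 712, and within slide 2 (4 against 2) limma called none, with 3186 genes at an unadjusted p under 0.05. Of 93 genes examined by name, 52 passed the test, and 7 of them did so whichever saline or hUMSC array was left out (controls were not left out here): Ccl12, Sele, Kcnj8, Xkr6, Htr2a, Ppp2r2c and Kcnj10 (-0.67 ± 0.13). Of the 52 calls, 45 were lost without saline replicate 1, 40 without saline replicate 5, 36 without hUMSC replicate 5, 32 without hUMSC replicate 6 or 7, 8 without hUMSC replicate 9, 3 without hUMSC replicate 10, 2 without saline replicate 3 and 1 without saline replicate 4. Of the 7 genes, Ccl12, Sele, Kcnj8 and Ppp2r2c were among the 23 genes called without saline replicates 1 and 5.

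Immune lists were higher in hUMSC than in saline. Antigen presentation rose in 13 of 19 members, or 19 adjusted over the list alone (median 0.85, adjusted p = 2.33e-11), with RT1-Da at 1.45 ± 0.35 and Cd74, the class II invariant chain, at 1.25 ± 0.33. Cytokines and chemokines rose in 11 of 27 and fell in 1, or 19 and 1 adjusted over the list alone (0.87, adjusted p = 7.01e-09), with Il1b at 1.70 ± 0.34 (1.11 with normexp) and Tnf at 0.84 ± 0.19. Leukocyte adhesion rose in 7 of 12, or 10 adjusted over the list alone (0.99, adjusted p = 5.64e-08), and the interferon response in 9 of 24, or 18 adjusted over the list alone (0.66, adjusted p = 7.13e-09). Phagocytic macrophages rose in 8 of 25, or 18 adjusted over the list alone (1.18, adjusted p = 1.16e-10), with Cd36, a scavenger receptor, at 1.92 ± 0.55. Complement rose in 5 of 19, or 15 adjusted over the list alone (0.71, adjusted p = 2.85e-08), T and NK cells in 5 of 16, or 7 adjusted over the list alone (0.54, adjusted p = 1.12e-05), and neutrophils in 4 of 9, or 6 and 1 lower adjusted over the list alone (1.03, adjusted p = 0.00419). S100a8 and S100a9 rose by 2.04 ± 0.57 and 2.06 ± 0.60. With an estimated correlation each of these 8 lists had an adjusted p = 0.276.

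Other lists rose as well. Proliferation rose in 3 of 26, or 26 adjusted over the list alone (median 0.93, adjusted p = 9.71e-11), reactive astrocytes in 4 of 22, or 9 adjusted over the list alone (0.81, adjusted p = 1.01e-08), with Gfap at 1.02 ± 0.29, and the matrix list in 6 of 27, or 8 adjusted over the list alone (0.72, adjusted p = 3.43e-09), with Col4a1, a basement membrane collagen, at 1.14 ± 0.27. Apoptosis and p53 rose in 8 of 26 and fell in 1, or 13 and 2 adjusted over the list alone (0.35, adjusted p = 9.52e-05). Endothelium and tight junctions rose in 6 of 17, or 8 and 1 lower adjusted over the list alone (0.34, adjusted p = 4.07e-05), with the growth factor receptors Kdr and Tie1 at 0.78 ± 0.15 and 0.84 ± 0.20. Pericytes and smooth muscle rose in 5 of 14, or 6 adjusted over the list alone (0.41, adjusted p = 0.000125), with Tagln at 1.16 ± 0.30. With an estimated correlation each of these 6 lists had an adjusted p = 0.276. Homeostatic microglia rose in 1 of 12, or 2 and 1 lower adjusted over the list alone (0.25, adjusted p = 0.0306, and adjusted p = 0.407 with an estimated correlation). Choroid plexus and ependyma rose in 1 of 15 by both counts (1 adjusted over the list alone; 0.25, adjusted p = 0.00191, and adjusted p = 0.291 with an estimated correlation), the member being Steap1, at 0.80 ± 0.23. With fry the calls of homeostatic microglia (adjusted p = 0.179) and of choroid plexus and ependyma (adjusted p = 0.109) were lost. Without saline replicates 1 and 5 the median was 0.42 for phagocytic macrophages, 0.24 for proliferation, 0.17 for reactive astrocytes, 0.55 for cytokines and chemokines and 0.49 for antigen presentation, between 0.12 (apoptosis and p53) and 0.47 (interferon response) for the other 9 rising lists that kept a call, and the calls of homeostatic microglia and neutrophils were lost.

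Neuronal lists were lower in hUMSC. General neuronal genes fell in 8 of 16, or 14 adjusted over the list alone (median -0.37, adjusted p = 4.07e-06, and adjusted p = 0.276 with an estimated correlation), with the neurofilament Nefl at -0.57 ± 0.13. Glutamatergic neurons and receptors fell in 8 of 21, or 10 adjusted over the list alone (-0.43, adjusted p = 2.10e-05, and adjusted p = 0.325 with an estimated correlation), with Camk2b at -0.69 ± 0.15 and the scaffold Homer1 at -0.73 ± 0.17. GABAergic interneurons and receptors fell in 7 of 21, or 10 adjusted over the list alone (-0.32, adjusted p = 2.72e-05), with Gad2, a GABA-synthesising enzyme, at -0.55 ± 0.14. Striatal projection neurons fell in 6 of 16, or 13 adjusted over the list alone (-0.53, adjusted p = 3.91e-05), with Pde10a at -0.83 ± 0.21. Potassium and sodium channels fell in 10 of 24, or 20 adjusted over the list alone (-0.47, adjusted p = 2.53e-07), with Kcnq3 at -0.92 ± 0.24. With an estimated correlation the last 3 lists each had an adjusted p = 0.285. Without saline replicates 1 and 5 the medians were -0.21 for the general, glutamatergic and GABAergic lists, -0.28 for striatal projection neurons and -0.26 for the channels. Not past the test were B cells (0.10, 0.779), red blood cells (-0.75, 0.140), resting astrocytes (-0.08, 0.448), mature oligodendrocytes (0.03, 0.241), oligodendrocyte precursors (-0.09, 0.591), heat shock, metallothionein and stress response (0.10, 0.141), cholesterol synthesis (-0.15, 0.0595), growth, neurotrophic and angiogenic factors (-0.02, 0.466) and immediate early genes (-0.09, 0.0850), each given as the median and the adjusted p. For the last 2 the mean (0.06 and 0.03) and the test were positive. Among genes given in every comparison, Mmp9 rose by 1.01 ± 0.30 (adjusted p = 0.0431), and Ccl2 (2.09 ± 0.67, adjusted p = 0.0517), Cd68 (1.32 ± 0.42, 0.0521), Hmox1 (1.24 ± 0.49, 0.0916), Hspb1 (1.24 ± 0.62, 0.157), Bdnf (-0.46 ± 0.29, 0.251) and Vegfa (-0.31 ± 0.18, 0.211) did not pass. The value of Vegfa is that of its probe with the highest mean. Its other probes had changes of -0.65, -0.52 and -0.41 (unadjusted p = 0.000433, 0.00246 and 0.0351). Within the growth factor list Angpt2, a vessel-destabilising factor, rose by 1.09 ± 0.26.

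The occlusion score placed each array between the controls (0) and the mean of the occluded arrays (1), over 1518 genes. It was 0.769 ± 0.358 (SD, n = 5) in saline and 1.19 ± 0.167 (SD, n = 6) in hUMSC, a difference of 0.423 (two-sided exact permutation p = 0.0260, smallest possible 0.00216). Saline replicates 1 and 5 scored 0.475 and 0.292, and the other saline arrays 1.01 to 1.05. The hUMSC arrays scored 0.977 to 1.37, above the highest saline array in 4 of 6. Without saline replicates 1 and 5 the difference was 0.153 (exact p = 0.167). The exact p was 0.0619 without saline replicate 5 and 0.0635 without hUMSC replicate 5, 6, 7 or 9. The difference was 0.504 within slide 1 (exact p = 0.1, 10 assignments) and 0.462 within slide 2 (exact p = 0.133, 15 assignments), where neither test could reach 0.05, and 0.479 with slide means removed (exact p = 0.0133).

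**Figure D3:**
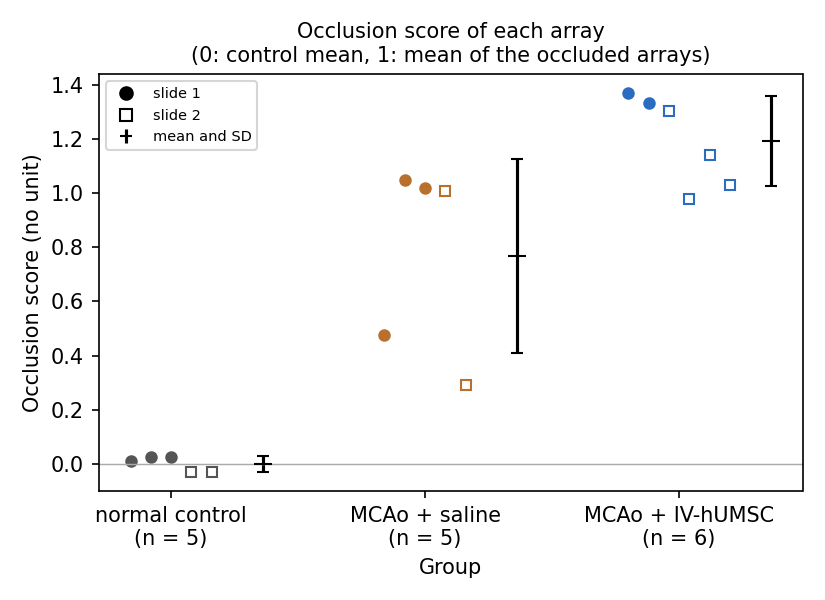
Occlusion score (no unit, vertical axis) of each of the 16 arrays by group; filled points are slide 1, open points slide 2, and bars show the mean and SD of a group. Saline replicates 1 and 5 sit at 0.475 and 0.292, and the 6 hUMSC arrays between 0.977 and 1.37.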

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

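The tests of dilution and the fits without saline replicates 1 and 5, without other pairs of saline arrays and with the occlusion score as a covariate were chosen after the values were seen. Of 285 groups of values tested for an array far from the rest of its group, 10 held such an array, against 14.25 expected by chance (1 in 20). Control replicate 3 was that array for 4 of them: S100a8 (-2.90, others -6.03 to -5.26), S100a9 (-1.91, others -5.23 to -4.44), Hmgcs1 (4.82, others 4.90 to 4.94) and Kcnj8 (-0.0428, others -0.22 to -0.19). The same array had the highest mean level of red blood cell genes, at 1.98. In hUMSC replicate 7, Slfn4 was at -0.58 (others -3.39 to -2.43) and Mx1 at 2.69 (others 0.49 to 1.15). Gpnmb was at -1.51 in control replicate 1 (others -1.77 to -1.72), Ccna2 at -4.55 in control replicate 2 (others -4.31 to -4.24), Aurkb at -3.80 in hUMSC replicate 8 (others -2.95 to -2.53) and Steap1 at -3.08 in control replicate 4 (others -2.71 to -2.65). These levels are log2 relative to the 75th percentile of the array.

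The number of genes called was compared with 100 splits of the same arrays, the real one included. Saline against control called 5581 genes, and 1 of the 100 splits, the real one, gave as many (highest other 2472). For hUMSC against control it was also 1 of 100, with 12700 genes and a highest other of 7573. In both comparisons no other drawn split gave as many calls. With 100 splits the share cannot fall below 1 in 100, so chance was not excluded more firmly than that.

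The hUMSC arrays lay farther from the controls than the saline arrays. Chance cannot be excluded for this: 5 of 100 splits of the occluded arrays gave as many genes as the 2624 called, with 4447 the highest other, which points to a structure among the arrays. A difference between slides is argued against as the whole cause by the 6390 genes called with slide as a block. A small response in saline replicates 1 and 5 remains a possible explanation, since 23 genes were called without them, against 64 to 6488 without each of the other 9 pairs of saline arrays. A single axis of response size is a possible explanation of part of the difference: the change from saline to hUMSC and the slope on the occlusion score within groups correlated at 0.894 over the called genes and 0.772 over all genes, the slope accounted for a median of 0.538 of the measured change, and whether infarct size or the infused cells moved the arrays along it was not measured.

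The neuronal lists fell after occlusion with the preset correlation, but not past the test with an estimated one (adjusted p = 0.226 to 0.365). The neuronal lists fell by 0.458 more than resting astrocytes and oligodendrocyte precursors together (exact p = 0.00794, the smallest possible). That reference leaves out mature oligodendrocytes, whose median change was -0.37, against -0.29 for the general and the GABAergic neuronal lists. The test therefore cannot decide whether incoming cells diluted all resident tissue equally. Equal loss or dilution of all neurons is argued against by the striatal list, which fell by 0.596 more than the general neuronal list (exact p = 0.00794). This holds only if the same region was sampled in both groups, and the labels do not give the region. The striatal list was the neuronal list with the largest median fall, so this p is no independent support. Loss of striatal neurons within the infarct and lower expression in surviving neurons could both give this difference of -0.596, and neither was tested.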

How the results depend on the processing

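The fits without saline replicates 1 and 5, with the occlusion score as a covariate, and of the lists, score and named genes within each slide were chosen after values were seen. No called change of a named gene, called list or summary value changed direction in the alternatives run, but the balance of calls turned with median scaling (saline against control from 52.4% to 32.7% higher, hUMSC against saline from 37.9% to 50.8%). In saline against control it also turned with quantile normalisation (43.5%), array weights (44.5%), a filter on all 16 arrays (48.6%), without saline replicates 1 and 5 (44.8%), without saline replicate 1 (3189 higher, 3303 lower) and without saline replicate 5 (3614 higher, 3990 lower). The number of genes higher in saline than control stayed within 1.5 times except within slide 2, where limma called 0 (2455 genes at an unadjusted p under 0.05 in both directions). The number lower was 4888 with median scaling, 5133 with array weights, 4992 without saline replicates 1 and 5, 973 within slide 1, 1 within slide 2, and 1154 to 3990 in leave-one-out fits. With a replicate block it was 1058; arrays of these groups that share a number correlated with each other at -0.05 to 0.18, and 2 of 5 correlated best with their own number, so the numbers were not taken as pairs. A replicate block with slide could not be fitted because each number lies on 1 slide.

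In hUMSC against saline the genes higher and lower were 428 and 935 with no filter on dim probes, 8 and 33 on the arrays of the 2 groups only, 2667 and 3723 with slide as a block, 327 and 712 within slide 1, 20 and 102 with array weights, and 5 and 18 without saline replicates 1 and 5. Limma called 0 and 0 within slide 2 (3186 genes at an unadjusted p under 0.05), and 0 and 0 with the occlusion score as a covariate. The covariate fit used the 11 occluded arrays only, and 1427 genes (6.97%) had an unadjusted p under 0.05. On the same arrays without the score 41 genes were called and 5813 had an unadjusted p under 0.05, so the drop to 0 is from 41. Leave-one-out fits gave 26 to 1796 higher and 157 to 2488 lower. Of the 2624 calls, 2624 were also made with slide as a block, 584 within slide 1 and 41 on the arrays of the 2 groups. Those 41 rest on the spread of the occluded arrays alone, and the full count also on the smaller spread of the controls (median SD 0.109 against 0.209 and 0.191). No paired analysis was possible because hUMSC shares only number 5 with the other groups. In hUMSC against control there were 3030 higher and 3154 lower within slide 2, and the other alternatives stayed within 1.5 times.

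With an estimated correlation 0 lists were called in each of the 3 comparisons, against 22, 21 and 22, although 20 of 20 simulated lists with a shift of 0.3 were called by it; simulated genes were independent, and the correlations estimated for the real lists ran from -0.06 to 0.90. The rotation test fry ended 1, 2 and 0 list calls in saline against control, hUMSC against saline and hUMSC against control, quantile normalisation 1, 0 and 0, and leaving out members of more than 1 list 1, 0 and 1 (heat shock and stress response). In the same order, 1, 1 and 0 list calls were lost within slide 1, and 0, 0 and 1 within slide 2. Score differences that lost the call were 0.411 with the lower genes only and 0.153 without saline replicates 1 and 5. Within slides 1 and 2 they were 0.504 and 0.462, where too few assignments exist to pass, and leave-one-out differences were 0.288 to 0.496. The correlation of the responses was 0.876 with the controls split. The cause was not tested where none is given. Of the named genes called, within slide 2 none of 73 (saline against control) and none of 52 (hUMSC against saline) passed in limma. With normexp the change was smaller by over 1.5 times for 21 of 73, 12 of 52 and 24 of 90 called named genes (saline against control, hUMSC against saline, hUMSC against control). Between 72.3% and 77.6% of probes were well above background, and with no filter on dim probes 26779 genes were tested instead of 20471.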

Other observations

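The lists in this part, the clock tests and the score covariate were chosen after values were seen, and gene names outside the naming rule are members of these lists. Genes of the lysosome, of iron and haem handling and of eicosanoid synthesis were higher after occlusion, although 3 of the 20 listed lysosomal, 3 of 12 iron and 1 of 13 eicosanoid genes also stand in lists of the report. In saline against control, lysosomal genes rose in 15 of 19 members, or 16 and 1 lower adjusted over the list alone (median 0.61, adjusted p = 6.94e-09, and adjusted p = 0.280 with an estimated correlation), with the protease Ctsz at 2.27, progranulin (Grn) at 1.70 and Ctsd at 1.29. Iron and haem genes rose in 8 of 12, or 8 and 2 lower adjusted over the list alone (0.63, adjusted p = 0.00296, and adjusted p = 0.280 with an estimated correlation), with the haem carrier Hpx at 3.08 and the ferritin light chain (Ftl1) at 0.69. Eicosanoid genes rose in 6 of 13, or 6 and 1 lower adjusted over the list alone (0.65, adjusted p = 0.00325, and adjusted p = 0.280 with an estimated correlation), with thromboxane synthase (Tbxas1) at 2.53. Neuropeptide genes fell in 7 of 16, or 8 adjusted over the list alone (-0.44, adjusted p = 0.0205, and adjusted p = 0.511 with an estimated correlation), with Crh at -1.08 and Penk at -0.85, and 7 of the 16 also stand in lists of the report. In the mitochondrial list 5 of 18 genes fell by both counts (5 adjusted over the list alone; -0.16, adjusted p = 0.00579, and adjusted p = 0.511 with an estimated correlation). Glycolysis and hypoxia (adjusted p = 0.455) and axon growth (adjusted p = 0.989) did not pass.

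In hUMSC against saline, eicosanoid genes rose in 3 of 13 members and fell in 1, or 6 and 1 adjusted over the list alone (median 0.34, adjusted p = 0.00231), with the prostaglandin synthase Ptges at 1.64 and Ptgs2 at -0.69. Lysosomal genes rose in 3 of 19, or 14 adjusted over the list alone (0.37, adjusted p = 5.22e-07), and iron and haem genes in 2 of 12, or 4 adjusted over the list alone (0.34, adjusted p = 0.00231). These 3 lists each had an adjusted p = 0.306 with an estimated correlation. Glucocorticoid-responsive genes were lower in 4 of 11 members by both counts (4 adjusted over the list alone; median -0.24, adjusted p = 0.0342, and adjusted p = 0.390 with an estimated correlation), with Zbtb16 at -0.81 and Fkbp5 at -0.56.

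Output genes of the circadian clock were lower in hUMSC than in saline in 4 of 9 members, or 5 adjusted over the list alone (median -0.38, adjusted p = 0.00155, and adjusted p = 0.306 with an estimated correlation), among them Per2 (-1.08 ± 0.22), Nr1d2 (-0.84 ± 0.12) and Dbp (-0.70 ± 0.14). A different time of day at sampling is a possible explanation that was not settled: Bmal1 and Npas2, of the opposite phase, rose relative to the output genes by 0.484 (exact p = 0.00433), but their own difference was 0.02 (exact p = 0.872). The list of 5 opposite-phase genes did not pass (adjusted p = 0.582): Clock and Cry1 fell by 0.44 and 0.43, and Bmal1, Npas2 and Nfil3 did not pass. With the occlusion score as a covariate the difference of the output genes was -0.161 (SE 0.0719). Their residuals on the score alone differed by -0.0921 (exact permutation p = 0.143). Removing the score without the group also removes part of the group difference, so that p does not test -0.161. Time of day and the response size cannot be told apart here. The labels give no time of day.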
